A study of Homo sapiens with 135 samples.

How the data were processed

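ChIP-seq of CTCF, MBD3, TET1, TET2 and TET3 was carried out in H9 cells on days 0, 4 and 9, with input samples of the same days and treatments. Libraries were sequenced as paired ends, per the labels' protocols, which name antibodies for CTCF, MBD3 and TET1. Samples were grouped by day, treatment and antibody from their titles, giving 45 groups, of which 9 were inputs.

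The deposited files were 36 peak lists, and per the labels each was called on replicates 1 to 3 pooled against a control. Which input served as control was not given in the sources used here. FastQC 0.11.7, Bowtie2 2.3.4, SAMtools 1.9, MACS2 2.1.2, bedtools 2.25.0 and build hg19 are named, without their roles, per the submitters' processing notes. For each peak the authors deposited the fold enrichment at the summit over the local background as a linear ratio, and the −log10 of the p-value and of the q-value. The highest q-value in the deposited lists was 0.05. These are the authors' values of single peaks and were used here to rank, filter or describe peaks within a list, not to compare enrichment between lists.

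Summit rows of 1 interval, 905026 over all lists, were collapsed to 1 region with the highest −log10 q. Regions of a pair of lists were shared when they overlapped by at least 1 bp. Control CTCF sites were merged regions with a CTCF peak in at least 2 of the 6 WT and DMSO lists, and the same sites moved by 10 kb gave the background. Where an alternative filtered the lists, the sites were redefined from the filtered CTCF lists. For CTCF itself the list compared with BPK25 was left out of the site definition. Random placement was the mean of 100 seeded draws within chromosomes. Lists were made equal in length by taking the regions of highest −log10 q up to the length of the shorter list, or, where treatments are compared, to 1 length for all of their lists, which was chosen after the data were seen. A pair was taken to have no room at equal length when the number of regions, as a percentage of the number of sites, was below the size of the whole-list difference. Ratios of shares were then compared, each at the length of its own pair of lists. They carry 95% intervals from counting error on the log scale and were also added after the data were seen. Shares carry Wilson 95% intervals, which cover counting error only. Ratios of region number were tested over antibody and day pairs with an exact two-sided sign-flip test of the mean. The same test on differences at CTCF sites, where none had been planned, was added after the shares were seen. Each list counts as 1 value, since replicates were pooled, and no p-value across peaks was computed. Lists of 1 day and treatment may share an input, so pairs were not fully independent.

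The lists state no depth. The pileup and local background at each summit were solved from the fold enrichment and −log10 p under a Poisson law, for rows of −log10 p up to 12. Between 89.8% and 100% of such rows per list gave a whole pileup within 0.01 in −log10 p, against at most 14.1% when p-values were shuffled among rows. The lowest background of a list was the lowest value found in at least 0.5% of its rows, a definition set after single rows were seen to give spurious lower values. It is a proxy that follows depth and fragment length together. The median pileup per list ranged from 7 to 29 fragments.

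Scripts ran on Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Overlaps were checked against bedtools 2.31.1 on the 20675 CTCF regions and the MBD3 regions of day 4 DMSO cells, where both counted 10910 CTCF regions with an overlap. On simulated data for those lists a planted overlap of 30.2% was recovered as 30.4%. All 798 pileups generated under the Poisson law were recovered from their fold enrichment and p-value. These values held no noise and came from the same law that was solved. Their backgrounds lay below the medians of 7.70 to 9.07 in the day 0 CTCF lists, which this check does not cover.

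Named regions were, per antibody and day, the 2 of highest −log10 q in each direction. One direction was a DMSO peak in the top 25% of its list with no BPK25 peak, and for CTCF and MBD3 also with a WT peak. The other was a BPK25 peak in the top 25% of its list with no DMSO peak, nor WT peak. The 2 control CTCF sites with peaks in most lists were added. The text names a few of these regions, picked after their values were seen. Alternatives fixed before the data were examined were a −log10 q of at least 5, a fold enrichment of at least 4, reciprocal overlap of at least 50%, a window of 500 bp, leaving out regions with peaks in at least 18 lists, unmerged summits, covered length, ranking by fold enrichment, 500 regions per list, sites in at least 4 control lists, lists of equal length and another expected overlap. Annotation and sequence of build hg19 were not used here, so promoters, the gene lists fixed beforehand and the CTCF motif were not analysed.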

Results

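Chromatin immunoprecipitation sequencing (ChIP-seq) maps where a protein sits on DNA. It was applied here to H9, an established human embryonic stem cell line, on days 0, 4 and 9 of neural induction, in which pluripotent cells are driven towards neural progenitors. The 5 targets were CTCF, the zinc finger protein that anchors chromatin loops, MBD3, a subunit of the NuRD chromatin remodelling complex, and TET1, TET2 and TET3, the enzymes that oxidise 5-methylcytosine. Cells were untreated (WT), given DMSO, or given BPK25 at 20 µM. The 135 samples comprised 108 immunoprecipitated and 27 input samples in 45 groups of 3 replicates, which are not stated to be separate cultures. WT cells were profiled for CTCF and MBD3 only.

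Each antibody, day and treatment was represented by 1 peak list called on its 3 pooled replicates, 36 lists in all. The values of a list therefore carry no replicate error, and the intervals given for shares are Wilson 95% intervals that cover counting error only. The lists held between 321 and 84203 regions, with a median of 15353. The lists state no depth. As a proxy, the lowest background recovered from each list lay between 0.38 and 3.36 overlapping fragments. Merged over all lists there were 350373 regions, of which 60.0% had a peak in 1 list only.

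The first comparison asked how the number of bound regions differed between BPK25 and DMSO. CTCF lists were shorter under BPK25 on each day, with 1296 against 1843 regions on day 0, 14500 against 20675 on day 4 and 3795 against 8469 on day 9. TET3 lists were also shorter on each day, and the day 9 list held 321 regions against 25543. TET1 lists were longer on each day, with 72148 against 8577 regions on day 0, 84203 against 45019 on day 4 and 43694 against 24572 on day 9. MBD3 had 590 against 7511 regions on day 0 and 15456 against 46132 on day 4, whereas the day 9 lists held 44297 and 44052. TET2 had 31522 against 3485 regions on day 0, but 13324 against 36633 on day 4 and 1928 against 15250 on day 9.

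**Figure D1:**
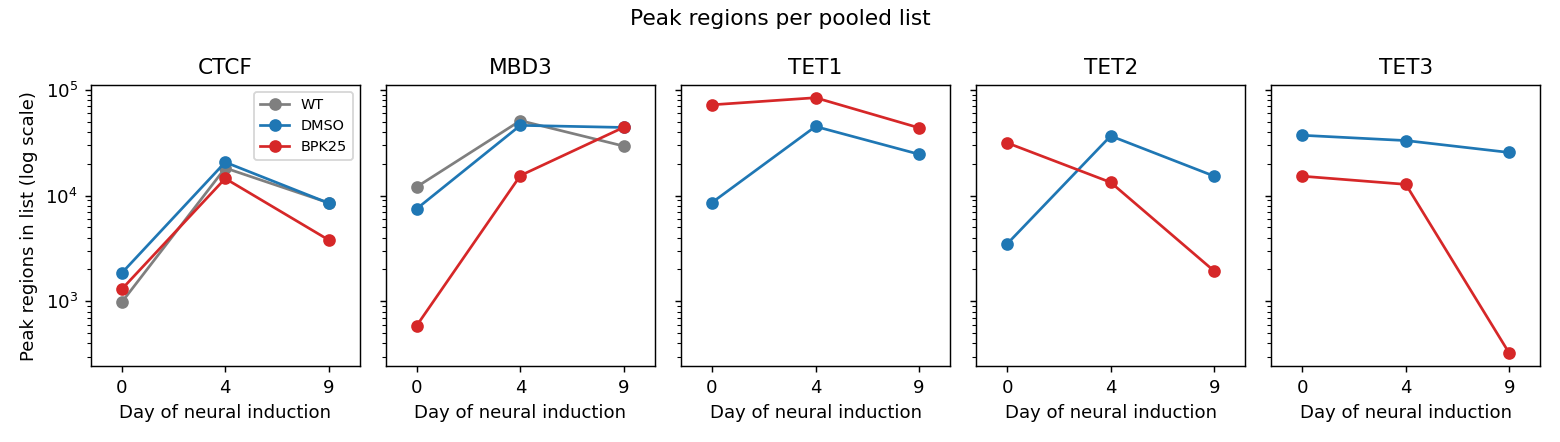
Number of peak regions in each pooled list (log axis) against the day of neural induction, with 1 panel per antibody and 1 point per list, coloured by treatment. TET1 lists were longer under BPK25 than under DMSO on each day, and the TET3 list of day 9 under BPK25 held 321 regions.

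Over the 15 antibody and day pairs the mean log2 ratio of region number, BPK25 over DMSO, was -0.86 ± 2.42 (SD, 15 pairs), lower in 10 pairs and higher in 5, and did not differ from 0 in an exact two-sided sign-flip test (p = 0.196). Among peaks of at least 4-fold enrichment the mean was -1.79 (exact sign-flip p = 0.0167). Such a cut depends on the background of each list. For MBD3 on day 4 the median background was 5.34 in BPK25 and 0.892 in DMSO, and 15.0% and 64.7% of regions passed. The value at this setting can therefore follow background as well as region number. Per antibody the mean over 3 days was -0.73 ± 0.37 (SD) for CTCF, -1.75 ± 1.84 for MBD3, 1.60 ± 1.27 for TET1, -0.42 ± 3.21 for TET2 and -2.99 ± 2.88 for TET3. With 3 days the smallest exact p is 0.25, so no single antibody could pass 0.05, and after Benjamini-Hochberg adjustment over the 5 antibodies the lowest exact p was 0.417. Between WT and DMSO, neither of which held the compound, the log2 ratios of CTCF and MBD3 lists reached 0.92 in size. TET1 had no WT lists, but its ratios of days 4 and 9, 0.90 and 0.83, lay within that range, while its day 0 ratio was 3.07. At 4-fold enrichment the TET1 ratios were 2.26, 0.29 and 0.48 on days 0, 4 and 9. The CTCF ratios of days 0 and 4, both -0.51, lay within the range between WT and DMSO, and the CTCF day 9 ratio was -1.16. That day 9 direction depended on how peak strength was measured. Among peaks of −log10 q of at least 5 the CTCF ratio was 0.76, whereas among peaks of at least 4-fold enrichment it was -2.66. For MBD3 on day 9 the ratio was -0.56 and -2.25 at these settings, against 0.008 with all peaks.

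The second comparison asked how often MBD3 and TET peaks lay at CTCF sites, the setting named in the title of the series, and how this differed under BPK25. Control CTCF sites were the 12295 merged regions with a CTCF peak in at least 2 of the 6 WT and DMSO lists. In DMSO cells MBD3 peaks covered 26.9% of these sites on day 0 (95% interval 26.1 to 27.7), 68.8% on day 4 (67.9 to 69.6) and 42.1% on day 9 (41.3 to 43.0). Under BPK25 the MBD3 shares were 2.71%, 35.8% and 32.2%. WT cells gave 18.0%, 55.7% and 39.3%, between the DMSO and BPK25 values on each day. With DMSO and BPK25 lists of equal length the MBD3 difference went from -32.9 to -8.11 percentage points on day 4 and from -9.98 to -10.1 on day 9. On day 0 both lists were then cut to 590 regions, 4.80% of the number of sites, so a difference of -24.2 points could not appear. As ratios of shares at equal length, BPK25 over DMSO was 0.644, 0.815 and 0.761 on days 0, 4 and 9, at 590, 15456 and 44052 regions. WT over DMSO, without the compound, was 0.451, 0.770 and 1.01, at 7511, 46132 and 29341 regions. Each ratio was taken at the length of its own pair, so the BPK25 and WT ratios are not like for like. They were added after the data had been seen.

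In DMSO cells TET proteins covered few control CTCF sites on day 0 and more on days 4 and 9. These sites were mostly not CTCF regions of day 0. With the day 0 DMSO list left out of their definition, that list had a CTCF peak at 7.97%. Of the CTCF regions in the DMSO list of the day itself, 33.7%, 30.1% and 32.5% held TET1, TET2 and TET3 on day 0. The shares were 26.8%, 26.0% and 26.5% on day 4 and 42.7%, 29.8% and 45.4% on day 9, so no rise was seen by day 4. At control sites TET1 was found at 4.10%, 35.1% and 31.2% on days 0, 4 and 9, TET2 at 3.06%, 34.3% and 20.9%, and TET3 at 4.41%, 35.0% and 36.1%. On day 4 the BPK25 shares at control sites were 22.8% for TET1, 5.07% for TET2 and 19.5% for TET3, and on day 9 they were 7.04%, 4.41% and 1.08%. TET1 peaks were thus found at fewer CTCF sites on days 4 and 9 although the TET1 lists were longer. The size of this depended on the setting, as the TET1 differences of days 4 and 9 were -12.3 and -24.2 percentage points with whole lists, -19.9 and -26.2 with lists of equal length, -1.51 and -15.0 at sites from BPK25 lists, and -1.93 and -2.72 with peaks of −log10 q of at least 5, where the DMSO shares were 6.88% and 5.08%. That last setting also redefined the sites from such CTCF peaks, giving 5448 sites. On day 4 equal lengths took the difference from -29.2 to -17.1 points for TET2 and from -15.5 to -3.99 for TET3. On day 9 the equal lists of TET2 and TET3 held 1928 and 321 regions, 15.7% and 2.61% of the number of sites, which left no room for differences of -16.4 and -35.0 points. The shares there were 4.41% in BPK25 against 5.72% in DMSO for TET2, a ratio of 0.771 (95% interval 0.691 to 0.860), and 1.08% against 1.81% for TET3, a ratio of 0.596 (0.482 to 0.738). On day 0 the BPK25 shares were 8.04% for TET1, 7.16% for TET2 and 4.78% for TET3, each above the DMSO value, but for TET1 and TET2 this turned with lists of equal length (-1.19 and -0.236 percentage points). At the same sites moved by 10 kb the shares lay between 0.0651% and 4.60%, and TET1 on day 0 had 4.06% there under BPK25 against 0.862% under DMSO.

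**Figure D2:**
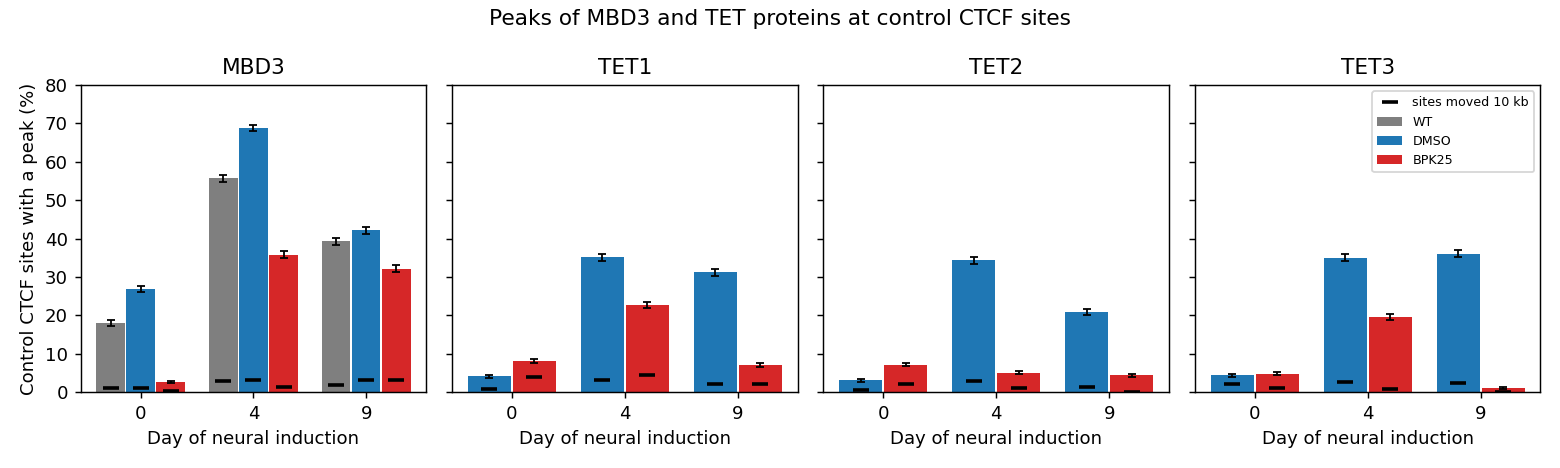
Share of the 12295 control CTCF sites (%) with a peak of MBD3, TET1, TET2 or TET3, by day and treatment, where error bars are Wilson 95% intervals and black dashes are the same sites moved by 10 kb. On days 4 and 9 each BPK25 bar lies below its DMSO bar, with 35.8% against 68.8% for MBD3 on day 4 and 1.08% against 36.1% for TET3 on day 9. With lists of equal length the MBD3 difference on day 4 was -8.11 points, and the TET3 lists of day 9, at 321 regions, were too short to show theirs.

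Over the 12 antibody and day pairs the share fell on average under BPK25, with a mean difference from DMSO of -15.9 ± 13.7 percentage points (SD, 12 pairs), lower in 9 pairs and higher in 3 (exact two-sided sign-flip p = 0.00391). This test was added after the shares had been seen, and its pairs share sites and may share inputs, so they are not independent. The size of the difference depended on the lists. With lists of equal length it was -7.42 points, but for MBD3 on day 0 and TET2 and TET3 on day 9 the cut lists left no room for the difference, and over the other 9 pairs it went from -12.9 with whole lists to -9.50. With peaks of −log10 q of at least 5 it was -8.43 points, from a mean of -27.2 for MBD3 (-22.4 with all peaks) and -2.18 for the TET proteins (-13.8 with all peaks), whose DMSO shares were at most 7.01% at that setting. The control sites were there redefined from such CTCF peaks, 5448 in place of 12295, so both the sites and the peaks changed. MBD3 in WT minus DMSO, without the compound, differed by -8.26 ± 5.14 points over 3 days (exact p = 0.25, the smallest possible).

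CTCF itself was measured on sites defined without the DMSO list of the day. On day 4 a CTCF peak was found at 54.7% of 5244 such sites in DMSO (53.4 to 56.1) and 47.9% in BPK25 (46.6 to 49.3). On day 9 the shares were 19.8% in DMSO and 23.4% in BPK25, of 10520 sites, and on day 0 they were 7.97% and 2.17%, of 11814 sites. On sites defined without the WT list of the day, WT gave 1.72%, 53.1% and 14.1% on days 0, 4 and 9 and BPK25 2.24%, 50.8% and 23.8%, so that BPK25 lay above WT on days 0 and 9, and on day 0 the comparisons with WT and with DMSO went in opposite directions. The mean difference, BPK25 minus DMSO, was -3.02 ± 5.72 points over 3 days (exact p = 0.5, smallest possible 0.25). Its sign turned with lists of equal length (2.23 points) and with peaks of −log10 q of at least 5 (0.117 points).

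CTCF regions of DMSO cells were then separated by whether the BPK25 list of the day had a CTCF peak there. At the 7932 day 4 regions with CTCF in both treatments, MBD3 was present at 71.8% in DMSO and 57.3% in BPK25, TET1 at 18.8% and 13.7%, TET2 at 19.5% and 1.98%, and TET3 at 19.7% and 13.0%. At the 12743 day 4 regions with CTCF in DMSO only, MBD3 was present at 40.9% and 8.37%, TET1 at 31.7% and 20.8%, TET2 at 30.0% and 3.23%, and TET3 at 30.7% and 11.2%. At the 1025 day 9 regions with CTCF in both, MBD3 was present at 78.6% and 70.9%, TET1 at 30.9% and 8.68%, TET2 at 26.7% and 8.88% and TET3 at 38.5% and 4.98%. At the 7444 day 9 regions with CTCF in DMSO only, the intervals of MBD3 overlapped, with 18.7% (17.9 to 19.6) in DMSO and 19.6% (18.7 to 20.5) in BPK25, while TET1 was present at 44.3% and 12.8%, TET2 at 30.3% and 4.39% and TET3 at 46.3% and 0.900%. On day 0 CTCF was found in both at 385 regions, where MBD3 was present at 67.8% and 46.2% and TET1 at 82.3% and 71.4%. TET2 was present there at 79.2% and 80.5% and TET3 at 78.2% and 81.6%, higher in BPK25 but with overlapping intervals. Many of these places were not particular to a condition. Of the 398 BPK25 CTCF regions that overlapped a DMSO region on day 0, 33.2% lay in regions with peaks in at least 18 lists, against 3.48% on day 4. At the 385 regions moved by 10 kb the shares were still 8.31% to 12.7%. At the 1458 day 0 regions with CTCF in DMSO only, MBD3 was present at 73.3% and 7.27%, TET1 at 20.9% and 20.4% and TET3 at 20.4% and 19.3%, while TET2 was higher in BPK25, with 17.1% (15.3 to 19.2) and 22.3% (20.2 to 24.5). These shares use whole lists, which differ in length, and the separation was made after the shares at control sites had been seen.

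The third comparison measured how many DMSO regions had a counterpart in another treatment. For CTCF 20.9% of DMSO regions on day 0, 38.4% on day 4 and 12.1% on day 9 overlapped a BPK25 region, against 29.1%, 39.9% and 14.6% for a WT region. For MBD3 the shares with BPK25 were 5.90%, 11.7% and 9.83%, against 55.4%, 49.2% and 19.02% with WT. The WT, DMSO and BPK25 lists of an antibody and day were then limited to the length of the shortest, a setting chosen after the data had been seen. At 590, 15456 and 29341 regions on days 0, 4 and 9, MBD3 overlap was 23.7%, 21.5% and 10.9% with BPK25 and 52.4%, 53.3% and 24.7% with WT. On day 4 this order turned among the 500 regions of highest −log10 q (BPK25 minus WT 22.6 points). CTCF overlap at 976 regions on day 0 was lower with BPK25 than with WT (21.8% and 40.1%), and at 14500 regions on day 4 it was higher (48.2% and 45.3%). On day 9, at 3795 regions, it was 20.1% with BPK25 and 12.6% with WT, an order that turned when regions were ranked by fold enrichment in lists equal only within each pair. For the TET proteins, which had no WT lists, DMSO and BPK25 lists of equal length overlapped by 6.76% (TET1, day 9, 24572 regions) to 34.4% (TET1, day 0, 8577 regions). The DMSO list enters the comparison with WT and that with BPK25, so their overlaps are not independent.

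**Figure D3:**
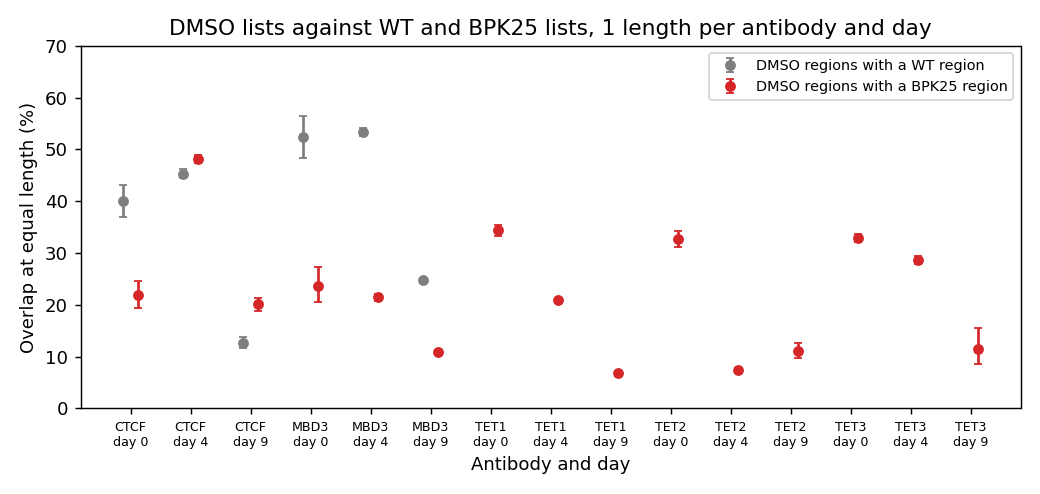
Share of DMSO regions (%) overlapped by a region of the WT or BPK25 list when all lists of an antibody and day are limited to the length of the shortest, for each antibody and day, with Wilson 95% intervals as error bars. Lengths differ between days, and at 590, 15456 and 29341 regions MBD3 overlap was 52.4%, 53.3% and 24.7% with WT and 23.7%, 21.5% and 10.9% with BPK25 on days 0, 4 and 9, an order that turned on day 4 with 500 regions.

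The bound regions also differed between days. Of CTCF regions of day 0, 54.2% in DMSO, 13.9% in WT and 15.0% in BPK25 were found again on day 4. To compare treatments, the lists of both days were limited to 1 length for all treatments of an antibody, a setting chosen after the data had been seen. At 976 regions the day 0 and day 4 CTCF lists then overlapped by 41.8% in DMSO, 6.66% in WT and 2.97% in BPK25, and those of days 0 and 9 by 30.9%, 5.84% and 3.28%. The day 4 and day 9 CTCF lists, at 3795 regions, overlapped by 18.8%, 8.14% and 48.4%. MBD3 lists at 590 regions overlapped between days 0 and 4 by 66.8% in DMSO, 32.9% in WT and 13.7% in BPK25, and between days 0 and 9 by 71.0%, 39.0% and 11.2%. Between days 4 and 9, at 15456 regions, it was 22.4%, 9.88% and 22.05%. TET1 lists overlapped more in BPK25 than in DMSO between days 0 and 4 (34.0% against 8.74%) and days 0 and 9 (29.8% against 3.801%), both at 8577 regions, and less between days 4 and 9 (21.1% against 30.9%, 24572 regions). TET2 lists overlapped more in BPK25 between days 0 and 4 (43.9% against 2.93%, 3485 regions), and less between days 0 and 9 (2.23% against 5.29%) and days 4 and 9 (3.79% against 17.8%), both at 1928 regions. For TET3 the overlap in BPK25 and DMSO was 1.46% against 2.44% between days 0 and 4 at 12757 regions, and at 321 regions it was 7.17% against 4.36% between days 0 and 9 and 11.8% against 23.1% between days 4 and 9.

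Within a condition the antibodies shared many regions. In DMSO cells on day 4, 52.8% of CTCF regions held an MBD3 region (52.1 to 53.4), against 1.03% with random placement on the same chromosomes, and 26.8%, 26.0% and 26.5% held TET1, TET2 and TET3. In BPK25 cells on day 4 the shares were 36.5% for MBD3, 16.5% for TET1, 2.02% for TET2 and 18.96% for TET3. On day 0 the TET shares were higher in BPK25 than in DMSO, at 61.9% against 33.7% for TET1, 66.2% against 30.1% for TET2 and 59.0% against 32.5% for TET3, and that of MBD3 was lower (17.8% against 72.2%). Of the day 0 CTCF regions, 21.5% in BPK25 and 9.17% in DMSO lay in regions with peaks in at least 18 lists. On day 9 CTCF regions held MBD3 at 26.0% in DMSO and 57.9% in BPK25, TET1 at 42.7% and 5.30%, TET2 at 29.8% and 4.80%, and TET3 at 45.4% and 1.61%. The shares can follow the lengths of the lists, which on day 0 were 72148 in BPK25 and 8577 in DMSO for TET1 and 590 and 7511 for MBD3. Ratios that set the overlap against list length were therefore compared. The first was the share over that of random placement. The second was the shared regions over those of independent lists among all merged regions. Neither removes length, since a longer list lowers the highest value either can reach. With random placement on day 0 TET1 gave 2.03% in BPK25 and 0.355% in DMSO, and TET3 0.451% and 1.05%. The day 0 orders of TET1 and TET3 in both ratios were therefore set by list length. In the second ratio this also holds for MBD3 on days 0 and 4, TET2 on day 0 and TET3 on day 9. For CTCF with TET1 both ratios were lower in BPK25 than in DMSO on each day. The first was 30.5 against 94.96 on day 0, 8.79 against 26.2 on day 4 and 5.43 against 61.9 on day 9, and the second 3.12 against 14.5, 0.892 against 2.47 and 0.550 against 7.0, so that under BPK25 on days 4 and 9 it fell below 1. For MBD3 both were higher in BPK25 on day 4 (90.6 against 51.1 and 8.66 against 4.43) and day 9 (48.1 against 24.5 and 4.78 against 2.36), whereas on day 0 they disagreed (10.8 against 47.9 and 98.8 against 34.7). For TET2 both were lower in BPK25 on day 4 (6.55 against 29.7 and 0.733 against 2.93), and they disagreed on day 0 (91.6 against 63.6 and 7.69 against 32.2) and day 9 (23.8 against 66.7 and 10.0 against 8.23). For TET3 both were higher in BPK25 on day 0 (131 against 30.9 and 14.2 against 3.11) and day 4 (58.4 against 32.4 and 6.20 against 3.25), and they disagreed on day 9 (9.84 against 59.1 and 18.0 against 7.09), when the BPK25 list held 321 regions.

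Regions were named by position on build hg19, by a rule fixed before the data were examined, and without gene annotation. The rule took 60 regions, of which 28 had peaks in at least 18 lists and 12 lay outside chromosomes 1 to 22 and X. On chromosome 22 the interval 43173161 to 43173390 headed the day 4 CTCF regions present in DMSO and WT and absent in BPK25, with 50.8-fold enrichment in the DMSO list. MBD3 had a day 4 peak at the same place (43173163 to 43173388) in DMSO and WT and none in BPK25. On chromosome 3 the interval 196625619 to 196625777 held a CTCF peak in DMSO and WT on day 0 and none in BPK25, and TET1 had a DMSO peak there (196625616 to 196625778) and none in BPK25. The CTCF peak had 6.81-fold enrichment at a −log10 q of 509. On chromosome 13 CTCF had a day 9 peak in BPK25 and none in DMSO or WT (82264343 to 82264523), while MBD3 had a day 9 peak in DMSO and WT and none in BPK25 (82264266 to 82264539). These peaks had 3.57-fold and 8.34-fold enrichment at a −log10 q of 627 and 970. On chromosomes 3 and 13, so high a −log10 q at so low a fold needs many fragments in the background too. Whether coverage there was abnormal was not examined. The 2 control CTCF sites with peaks in most lists, on chromosome 1 (121484391 to 121485429) and chromosome 5 (10025 to 11788), had a peak in all 36 lists. Every antibody thus had a peak there in every condition, so these places are not particular to CTCF and are no evidence of constant CTCF binding. Without replicates a region absent from a list was not detected in those pooled libraries, which does not show that it was unbound.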

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

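The tests of differences between antibodies, of depth, of peaks close to the threshold, of local background and of separate parts of a pattern were chosen after the results were seen, while those over 8 pairs with lists of equal length and with sites from WT lists were chosen before theirs.

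TET1 and CTCF lists differed from DMSO in opposite directions under BPK25 on 3 of 3 days, with mean log2 ratios of region number of 1.60 and -0.73, a difference of 2.33. Among peaks of −log10 q of at least 5, however, both were longer under BPK25 on day 9 (0.29 and 0.76). TET1 and TET3 mean ratios differed by 4.59. In an exact permutation test of 3 days against 3 days, which ignored the pairing by day, both gave p = 0.1, the smallest that test allows. A sign-flip test paired by day could give no exact p below 0.25. TET2 was higher under BPK25 on day 0 and lower on days 4 and 9, a difference of 5.40 in log2 ratio that was not tested. At control CTCF sites the 3 TET proteins differed between BPK25 and DMSO by 2.81 percentage points on average on day 0 and by -22.1 on days 4 and 9, which are 24.9 points apart. A permutation of days would be void here and the difference counts as not tested, since the day 0 shares under DMSO were 3.06% to 4.41%, which left no room for a fall of that size, and the day 0 direction turned for TET1 and TET2 with lists of equal length (-1.19 and -0.236 points).

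On days 4 and 9, which were set apart after day 0 was seen to differ, fewer control CTCF sites had MBD3 and TET peaks under BPK25 in 8 of 8 pairs. List length was argued against for the 3 pairs whose BPK25 list was at least as long, with a mean of -15.5 points. It was also argued against for TET2 on day 4, where the ratio of shares at equal lengths, BPK25 over DMSO, was 0.228 at 13324 regions. The lowest ratio of MBD3 lists without the compound, WT over DMSO, was 0.451, but at 7511 regions and for another antibody. List length cannot be told apart for MBD3 and TET3 on day 4 (0.815 and 0.830) and TET2 and TET3 on day 9 (0.771 and 0.596). Their ratios lay between 0.451 and 1. The mean of 8 pairs at equal lengths, -10.9 points, decides nothing, since the cut lists of TET2 and TET3 on day 9 left no room for their differences. Use of DMSO lists in defining sites was argued against as the whole cause for the TET proteins, with a mean of -35.9 points at sites from WT lists, and for MBD3 on day 4 (-54.0, counting interval -56.5 to -51.5), but the size depended on the lists, since at sites from BPK25 lists these were -11.7 (range -26.1 to -1.51) and -8.07, and it cannot be told apart for MBD3 on day 9, with 0.885 at WT and -9.35 at BPK25 sites, nor therefore for MBD3 over both days (mean -26.6 at WT sites) or all 8 pairs (-33.6). A raised local background in BPK25 lists cannot be told apart from lower occupancy, which stays open as a hypothesis. The background at peaks relative to the lowest background was higher in BPK25 than in DMSO in each of the 8 pairs. It was 1.54 to 2.64 in BPK25 and 1.07 to 1.25 in DMSO, which goes with a raised background. Where CTCF was called in both treatments the mean difference was -15.6 points, but CTCF peaks can pass a background that weaker peaks do not.

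TET1 lists were longer under BPK25 on 3 of 3 days. The depth proxy was not higher in BPK25 on days 4 and 9, where the lowest background was at most 0.934 times that of DMSO (0.604 at the lowest). That proxy also follows fragment length and has no spread, so greater depth was not excluded. On day 0 the ratio was 1.60, which goes with greater depth in BPK25, so depth cannot be told apart there. The lowest value of any row gave 0.202, but single rows were seen to give spurious lower values, so this does not offset it. Among peaks of −log10 q of at least 5 the log2 ratio was 2.00, 0.89 and 0.29 on days 0, 4 and 9 (mean 1.06). On day 0 this argued against peaks close to the threshold as the whole cause. The ratios of days 4 and 9 decide nothing. They lay within the 0.92 by which CTCF and MBD3 lists of all peaks differed between WT and DMSO. Greater depth, which was not excluded, could also raise the −log10 q of peaks. An effect of BPK25 on TET1 binding stays open, as untested.

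CTCF lists were shorter on day 0 than on day 4 in all 3 treatments. The depth proxy was not lower on day 0, where the lowest background was at least 1.73 times that of day 4. That proxy also follows fragment length and is read from called peaks only. On day 0, 9.51%, 2.39% and 2.69% of the solved rows lay at the lowest background in WT, DMSO and BPK25. On day 4 it was 16.6%, 27.3% and 7.62%. The short day 0 lists may therefore miss the true lowest background, so shallower day 0 libraries were not excluded. A raised local background on day 0 cannot be told apart from the day itself, since the background at peaks relative to the lowest background was at least 1.39 times that of day 4 in each treatment. A difference between days in CTCF binding stays open, as untested.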

How the results depend on the processing

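The settings that used sites from WT lists, from BPK25 lists, from other days or where CTCF was called in both treatments, chromosomes 1 to 22 and X alone, 1 list length over all treatments, ratios and pairs with room at equal length, and the lowest background of any row were chosen after seeing the data, as was the sign-flip test at CTCF sites. Pairs in the tests were antibody and day. By replicate number, no paired analysis was possible because replicates were pooled before peak calling, which also ruled out leaving out each replicate. Promoter shares, fixed gene lists and the CTCF motif were not run. The mean difference of MBD3 and TET at CTCF sites stayed below 0 and past its threshold under all 11 alternatives, from -23.1 points (sites from WT lists) to -7.42 points (equal lengths, at which 3 pairs had no room for their difference, and -9.50 without these), and with −log10 q of at least 5 it was -8.43. The mean log2 ratio of region number passed the threshold at 4-fold enrichment only, at -1.79, a cut that depends on the background of each list. The median list held 4848.5 regions at −log10 q of at least 5, 7817 at 4-fold enrichment, and covered 4304 kb. With reciprocal overlap of at least 50%, a window of 500 bp, −log10 q of at least 5 and without regions in at least 18 lists, in that order, the median share of DMSO regions with a BPK25 region (12.1%) became 9.20, 15.7, 20.0, 11.3%, that with a WT region (34.5%) 29.1, 38.5, 47.1, 32.3%, and the overlap of equal lists (21.5%) 16.2, 24.2, 27.7, 20.0%. Ranked by fold enrichment that overlap was 13.6%, and with 500 regions 24.4%. The median overlap between days was 8.26% with reciprocal overlap, and the median co-occupancy ratio was 3.45 against independent lists in place of 30.6. CTCF at CTCF sites was -1.03 points with reciprocal overlap and -0.967 with sites of other days, and reversed to 0.117 with −log10 q of at least 5 and 2.23 with equal lengths (0.362 on day 4). Further reversals were the region number of CTCF on day 9 with −log10 q of at least 5 (0.76), that of MBD3 on day 9 with −log10 q of at least 5 (-0.56), 4-fold enrichment (-2.25), without recurrent regions (-0.00218) and on chromosomes 1 to 22 and X (-0.000921), and the order of BPK25 and WT overlap for MBD3 on day 4 with 500 regions (22.6 points) and CTCF on day 9 ranked by fold enrichment (-0.463). At CTCF sites MBD3 on day 9 reversed with sites from WT lists (0.885). On day 0 TET1 reversed with −log10 q of at least 5, equal lengths and CTCF called in both (-0.918, -1.19, -10.9), TET2 with −log10 q of at least 5 and equal lengths (-0.184, -0.236), and TET3 within 500 bp (-0.0651). Against independent lists the log2 co-occupancy ratio reversed for MBD3 with TET3 on day 0 in DMSO (-0.46) and, under BPK25, for CTCF with TET1 and TET2 on day 4 (-0.16 and -0.45) and with TET1 on day 9 (-0.86). For these the cause was not tested. Of the other values, for single antibodies and days and a few means over them, 167 stayed within their limits and 228 moved with the same sign. The lists state no depth, so what depth limits was not measured, and they give no replicate error.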

Other observations

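The values in this part were examined after the results were seen, and none was tested, and they rest on whole lists that differ in length. TET1 regions found under BPK25 and not in DMSO mostly lay away from CTCF sites. Of the 67511 such regions on day 0, 0.973% lay in a control CTCF site, against 0.659% in the same sites moved by 10 kb. On day 4 it was 0.873% of 69330 against 0.622%, and on day 9 0.802% of 41027 against 0.600%. Of TET1 regions found in DMSO and not BPK25, 4.23% of 3712 on day 0, 6.97% of 30235 on day 4 and 15.2% of 21903 on day 9 lay in a control CTCF site. In the moved sites these shares were 1.29%, 0.794% and 0.977%. Of the BPK25 TET1 regions that overlapped a DMSO region, 7.48%, 15.2% and 20.2% lay in a control site. A BPK25 peak of another antibody was found at 21.1%, 12.6% and 21.3% of the TET1 regions found under BPK25 only on days 0, 4 and 9. On day 9, 21.1% held an MBD3 peak and 0.173% a CTCF peak.

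For CTCF the order depended on the day. Of the CTCF regions found under BPK25 only, 19.6% of 898 on day 0, 7.88% of 6675 on day 4 and 60.3% of 2781 on day 9 lay in a control CTCF site. Of those found in DMSO only, 78.2% of 1458, 32.1% of 12743 and 39.5% of 7444 did, where the DMSO list itself helps to define the sites. Of the BPK25 CTCF regions that overlapped a DMSO region, 82.4%, 75.1% and 94.0% lay in a control site. Of the day 0 regions found under BPK25 only and in DMSO only, 16.4% and 2.54% lay in regions with peaks in at least 18 lists. On day 0, TET1, TET2 and TET3 peaks of the same treatment were found at 57.9%, 59.6% and 48.8% of the CTCF regions found under BPK25 only, and at 20.9%, 17.1% and 20.4% of those found in DMSO only. On day 9 they were found at 4.14%, 3.38% and 0.503% of the former and 44.3%, 30.3% and 46.3% of the latter.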
